A study of Mus musculus with 12 samples.

How the data were processed

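Whole-genome bisulfite (BS) and oxidative bisulfite (oxBS) libraries were compared between nuclear fractions of the mouse retina. Per the labels, the mice carried a tamoxifen-inducible Cre recombinase under the Aldh1l1 promoter, which is active in Müller glia, the radial glia of the retina, and the NuTRAP reporter, which biotinylates the nuclear envelope of recombined cells. Nuclei of 2 retinae were pooled per sample, 10% were kept as the input fraction of the whole retina, and the rest were passed over streptavidin beads, whose bound nuclei form the positive fraction. Each of 3 animals, numbered 12, 40 and 55 in the labels, gave 1 input and 1 positive DNA sample, and each DNA sample gave 1 BS and 1 oxBS library, 12 libraries in all. BS libraries read 5-methylcytosine (5mC) and 5-hydroxymethylcytosine (5hmC) alike as methylated. The oxidation step of oxBS turns 5hmC into a base that reads as unmethylated, so oxBS libraries read 5mC alone, and the BS level minus the oxBS level of the same DNA estimates 5hmC. Both estimates use the oxBS level, so a shift in it moves 5mC and 5hmC in opposite directions. No controls for conversion or oxidation were among the files used here, so the efficiency of both steps is unknown. Incomplete oxidation would raise the oxBS level and lower the 5hmC estimate, and incomplete conversion would raise the level of both kinds of library.

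Per the submitters' processing notes, the tools used were Trimmomatic 0.35, Bismark 0.22.3 with Bowtie2 2.3.1, FastQC and methylKit, and the build was GRCm38 (mm10). The notes as used here give neither the role nor the settings of each tool, so trimming, removal of duplicate reads and any coverage filter are not given in the sources used here. The deposited tables have no header, and each of their lines holds a CpG position with its strand, the percent of calls methylated and the coverage as a count of calls. The deposited percent is rounded to 0.1 points, and percent times coverage gave a whole number of methylated calls within a rounding tolerance of 0.05 points in all but 387 of 100315790 lines. Calls without molecular identifiers are not independent molecules, and neighbouring positions of a read share a molecule, so counting intervals cover counting error only.

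Depth was low. A library held 6540746 to 10873897 covered positions and 10672306 to 16372037 calls, or 1.44 to 1.65 calls per covered position. Positions with 1 call made up 67.8% to 71.5% of a BS library and 57.5% to 59.2% of an oxBS library, and 0.297% to 0.670% of positions had 5 or more calls. Positions above the 99.9th percentile of coverage, which was 6 calls in every library, were dropped. They held 5.71% to 6.61% of the calls, and the highest coverage of a library was 25191 to 29777. Single positions were therefore not tested, and calls were summed over regions. A region entered a test with at least 5 positions and 30 calls in every library of the comparison. Libraries of 1 group shared 18.0% to 27.6% of the smaller library's positions over 12 pairs.

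Regions were taken from the NCBI RefSeq annotation of GRCm38.p6, the build of the files, which as used here holds gene spans without strand, exons or untranslated regions. Promoters, exons and introns had been planned as classes and were replaced. A gene end was called CpG-dense when the 2 kb window around it, 1 kb to either side, held at least 2 times the CpG positions of the window around the other end, which gave a dense end to 13121 of 21883 protein-coding genes and stood in for the promoter. A dense end was not checked against transcription start sites. The gene body was the gene without 1 kb at either end, for the 19300 genes longer than 2 kb. Genome classes were the dense ends, the rest of protein-coding genes, and the sequence outside them. Fixed tiles of 2 kb were tested and were also grouped by their number of CpG positions. Genes whose spans overlap share calls, since calls cannot be assigned to 1 of them.

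Levels of the genome and its classes were compared between the fractions by an exact permutation test, two-sided, with the 3 input against the 3 positive samples of the same 3 animals, for which the smallest possible p is 0.1. That test leaves out the pairing by animal. An exact sign-flip test of the within-animal differences keeps the pairing, and its smallest possible p is 0.25. Regions were tested for 5mC in oxBS libraries, and for the total of 5mC and 5hmC in BS libraries, with a quasi-binomial logistic model of methylated and unmethylated calls, whose overdispersion was moderated across regions with limma's empirical Bayes step and not allowed below 1. The same model compared BS with oxBS libraries within a fraction. The 5hmC level of each DNA sample was compared between fractions with limma. All region tests were two-sided with Benjamini-Hochberg adjustment, and a region was called at an adjusted p under 0.05. Each comparison used only its own 6 samples. Libraries of the same number come from the same animal, so the numbers pair the samples. Across gene bodies, the correlation of same-animal deviations from the group means ran from -0.0213 to 0.00466 over the 3 animals and both measures. The main model left the animal out, and a fit with the animal as a block was run beside it.

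The 17 gene lists, with 270 entries all found in the annotation, were fixed before the data were examined. They covered markers of Müller glia, rods, cones, bipolar, amacrine, ganglion and horizontal cells, microglia, vascular cells, astrocytes and the retinal pigment epithelium, the DNA methylation machinery, reactive gliosis, neurogenic factors, imprinted genes, housekeeping genes and Hox genes. Lists were tested with limma's cameraPR at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The genes named were also set by a rule fixed before the data were examined. It took the 10 called genes with the largest difference per direction, up to 4 called members per list or, with none called, the 2 members with the largest difference, and in every case a fixed set of genes that included Aldh1l1, Glul, Rlbp1, Nrl, Tet1, Tet2, Tet3, Dnmt1 and Dnmt3a. The comparison of list levels with other genes, the ranking of genes by 5hmC, the description of the X chromosome and the extension of the naming rule to BS against oxBS were chosen after the data were seen.

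Alternatives fixed before the data were examined were the animal as a block, minimums of 5 and 10 calls per position, stricter and absent region minimums, no upper coverage limit, autosomes only, centring on the library's genome level, equal weight for each position, the positions covered in all 12 libraries, other windows and tile sizes, limma on percent levels, edgeR's quasi-likelihood test on methylated and unmethylated counts, coverage weights, a quasi-binomial interaction for 5hmC, and leaving out each DNA sample. Summing the calls of both chemistries per DNA sample was added after seeing the data. The region tests were tested on simulated data with calls drawn at the real depth and spread and 200 regions changed. Changes of 10, 20, 30 and 40 points were called in 22%, 62%, 90% and 100% of gene bodies for 5mC and in 0%, 8%, 52% and 66% of gene bodies for 5hmC, with 50 regions per size. For dense ends the shares were 16%, 60%, 72% and 94% for 5mC and 10%, 26%, 68% and 78% for 5hmC, and for 2 kb tiles 2%, 20%, 50% and 70% for 5mC and 0%, 28%, 50% and 70% for 5hmC. For BS against oxBS in the gene bodies of input they were 16%, 64%, 80% and 94%. There the changed gene bodies were drawn from those with an oxBS level under 60%, and the BS level was raised. The real comparison called 7505 of 13905 gene bodies, far more than the 200 changed here, so these shares need not hold for it. For 5hmC between the fractions the BS level was moved, downward where the oxBS level was above 50%, which can give a 5hmC level below 0. Of the regions called in these simulations, 10 of 147 were unchanged ones (6.80%, above the nominal 5%) for 5mC in gene bodies, 3 of 66 for 5hmC in gene bodies, 0 of 121 and 4 of 95 for 5mC and 5hmC at dense ends, 0 of 71 and 1 of 75 in tiles, and 6 of 133 for BS against oxBS. With nothing changed, 0 regions were called in each comparison of the fractions and 1 for BS against oxBS. Statistics were computed in R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.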

Results

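DNA methylation and hydroxymethylation were read at CpG positions across the mouse genome in 2 fractions of retinal nuclei. The input fraction held nuclei of the whole retina, and the positive fraction held the nuclei bound by streptavidin. The tag was meant to bind nuclei of cells in which Aldh1l1-driven Cre had been active. How far the positive fraction was enriched in them was not measured here, so its results are those of the bound nuclei. Each fraction had 3 animals, numbered 12, 40 and 55, and each DNA sample had a BS library and an oxBS library, so each of the 4 groups of libraries had n = 3. In animals 12, 40 and 55, the BS libraries of input held 11825071, 16372037 and 14973728 calls and its oxBS libraries 13465881, 10936484 and 12420170 calls. The BS libraries of the positive fraction held 15015825, 13460177 and 13588748 calls and its oxBS libraries 10995805, 10672306 and 10925608 calls. These calls were spread over 20749745 CpG pairs seen in any library, and 5817 positions were covered in all 12 libraries, so levels were read from regions and not from single positions.

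The first comparison asked whether the positive fraction differed from the whole retina in its overall level of each mark. Of all CpG calls, 70.5% ± 0.25 (SD, n = 3) carried 5mC in input and 69.7% ± 0.401 in the positive fraction. The 5hmC level was 8.19% ± 0.278 in input and 8.64% ± 0.304 in the positive fraction. The genome-wide 5mC level was lower in the positive fraction in 2 of 3 animals, by a mean difference of -0.710 points (exact permutation p = 0.2, two-sided), and 5hmC was higher in 2 of 3 animals, with a mean difference of 0.449 points (exact p = 0.3). The sum of both marks was 78.6% ± 0.174 in input and 78.4% ± 0.0976 in the positive fraction, lower in 3 of 3 animals, with the smallest exact p that 3 against 3 allows, 0.1. None of these differences passed, and the exact permutation test used here cannot give a p below 0.1 with 3 against 3. With at least 5 calls per position the 5mC difference was -1.23 points (exact p = 0.1), and on the positions covered in all 12 libraries it had the other sign, 0.40 points (exact p = 0.6). The 5hmC difference was 0.289 points without the input sample of animal 40 and 0.289 to 0.624 points over all omissions of 1 sample. On the positions covered in all 12 libraries it was 0.936 points (exact p = 0.3), at 5hmC levels of 0.489% ± 0.406 in input and 1.42% ± 0.982 in the positive fraction.

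Both marks depended strongly on the kind of sequence. Protein-coding genes outside their CpG-dense ends carried 71.1% ± 0.169 5mC and 9.83% ± 0.208 5hmC in input (SD, n = 3). In the positive fraction these gene regions had 70.4% ± 0.279 5mC, lower in 3 of 3 animals, and 10.3% ± 0.276 5hmC, higher in 3 of 3 animals, each with the smallest possible exact p of 0.1 and an adjusted p of 0.2. The sign-flip p was 0.25 for both, the smallest possible. The 5hmC estimate is the BS level minus the same oxBS level, so these are not independent results. The oxBS level differed by -0.685 points, the BS level by -0.198 and 5hmC by 0.487. A difference in oxidation could move both marks this way and was not tested. With at least 5 calls per position the differences were -1.53 points of 5mC and 1.27 points of 5hmC (exact p = 0.1 for both). Sequence outside genes held more 5mC and less 5hmC, with 77% ± 0.0595 and 5.88% ± 0.0828 in input and 76.7% ± 0.300 and 6.19% ± 0.271 in the positive fraction (exact p = 0.2 and 0.3, adjusted 0.356 and 0.48). CpG-dense gene ends had 8.76% ± 0.393 5mC in input and 8.45% ± 0.611 in the positive fraction. Their 5hmC was 3.93% ± 0.0472 and 3.94% ± 0.0643 (exact p = 0.6 and adjusted p = 0.64 for both marks). These ends include those on the X chromosome, whose 5mC in input was 16.4% in animal 12 and 43.1% in animal 40. On autosomes alone, 5hmC at dense ends was 3.84% ± 0.0598 in input and 3.93% ± 0.0171 in the positive fraction. It was higher in 3 of 3 animals (exact p = 0.1, unadjusted). The autosomal 5mC difference was -0.258 points (exact p = 0.2). At X ends the 5hmC difference was -1.44 points, lower in 3 of 3 animals (exact p = 0.2). Across 2 kb tiles of input, 5mC ran from 80.6% in tiles with under 10 CpG positions to 7.09% in tiles with 80 or more, while 5hmC was highest, at 8.63% ± 0.0439, in tiles with 20 to 39 CpG positions and 3.45% ± 0.0557 in the densest tiles. The levels of the positive fraction in the same tiles were 80.4%, 6.90%, 9.07% ± 0.237 and 3.43% ± 0.108, and no class of tiles reached an adjusted p below 0.2.

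**Figure D1:**
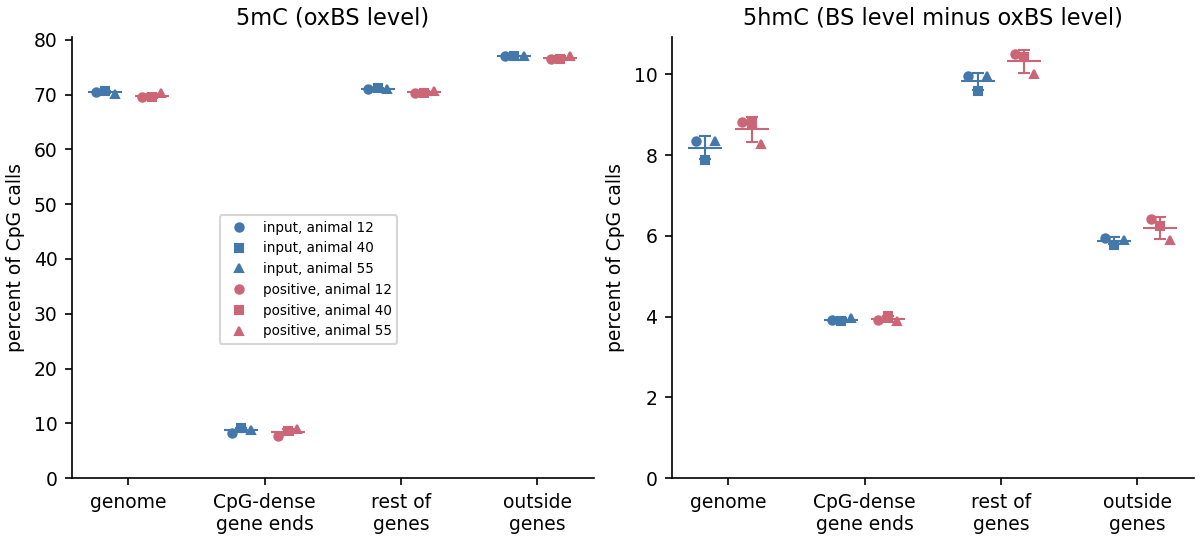
The y axes give 5mC and 5hmC as percent of CpG calls for the genome, CpG-dense gene ends, the rest of genes and the sequence outside genes. Symbols are the 3 animals of the input and positive fractions, bars the mean and SD, and 5hmC was 9.83% in input and 10.3% in the positive fraction in the rest of genes against 3.93% and 3.94% at dense ends.

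Around the CpG-dense gene ends, 5mC formed a trough with a shoulder of 5hmC on both sides. Outside the gene, from -1.5 to -1 kb, 5hmC was 11.4% ± 1.59 in input and 11.9% ± 0.597 in the positive fraction. From -4 to -3.5 kb it was 8.94% ± 0.514 and 9.27% ± 0.897. In the first 500 bp on the gene side, 5mC was 4.50% ± 0.392 in input and 4.19% ± 0.712 in the positive fraction, and 5hmC was 1.94% ± 0.189 and 1.95% ± 0.137 (SD, n = 3). From 2 to 2.5 kb into the gene, 5hmC was 12.5% ± 1.33 in input and 13.9% ± 0.749 in the positive fraction, at 5mC levels of 52.0% ± 1.37 and 50.9% ± 0.152. From 2.5 to 3 kb, 5hmC was 13.1% ± 0.0969 and 13.5% ± 0.251. At 9.5 to 10 kb into the gene, 5mC had come to 66.6% ± 0.378 in input and 66.1% ± 0.721 in the positive fraction, and 5hmC was 10.8% ± 0.232 and 11.3% ± 0.625. The bins of the profile were described and not tested.

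**Figure D2:**
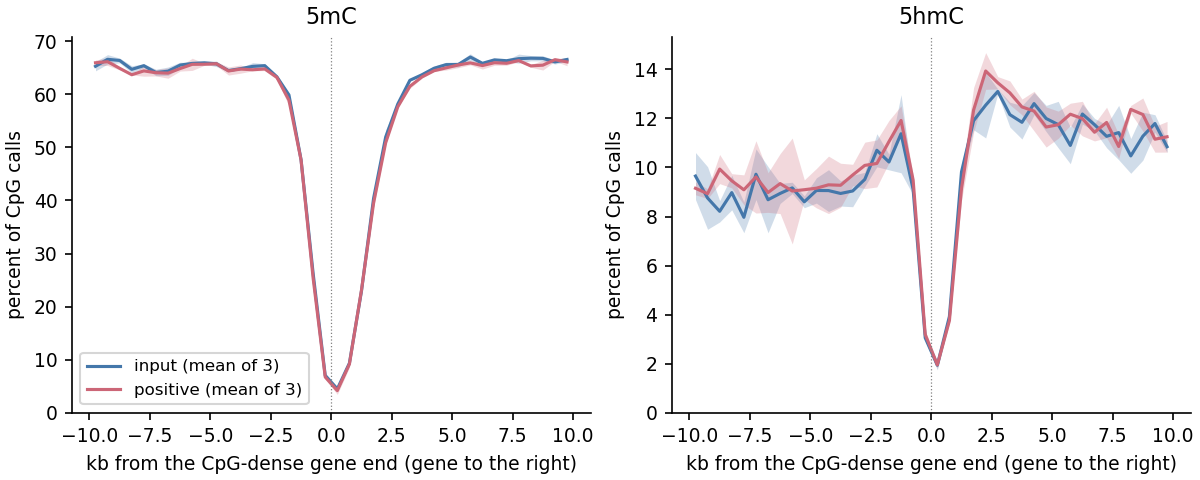
The x axis gives the distance from the CpG-dense gene end in kb, with the gene to the right, and the y axes 5mC and 5hmC as percent of CpG calls in bins of 500 bp. Lines are the means of 3 animals of the input and positive fractions and bands their SD, and in the bin from 2.5 to 3 kb inside the gene 5hmC was 13.1% in input and 13.5% in the positive fraction.

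The next comparison asked which gene bodies differed in 5mC between the positive fraction and the whole retina. One gene body did. Myo15b, which encodes an unconventional myosin, carried 74.8% ± 2.22 5mC in input and 50.2% ± 4.69 in the positive fraction (SD, n = 3), a difference of -24.7 points that was lower in 3 of 3 animals (quasi-binomial adjusted p = 0.0155). The Myo15b gene body lies on chromosome 11 of GRCm38, from 115858925 to 115891617, spans 635 CpG positions, overlaps Recql5 and had at least 254 calls in every library. Its 5hmC was 3.68% ± 2.77 in input and 21.1% ± 10.1 in the positive fraction (limma adjusted p = 0.899), and its sum of both marks was 78.5% ± 0.820 and 71.2% ± 5.42 (quasi-binomial adjusted p = 0.917). Leaving out 1 sample left the Myo15b difference at -27.3 to -22.9 points, while the call changed. It was kept without the positive sample of animal 12 (adjusted p = 0.00953) and lost without input 12 (0.0687), input 40 (0.0698), input 55 (0.540), positive 40 (0.0611) or positive 55 (0.159). In the 200 bp bins covered in both fractions, the Myo15b difference was -16.3 points, of which -13.1 came from which bins were covered and -3.25 from levels within bins.

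In the remaining gene bodies no 5mC difference was called. Of 13524 gene bodies tested, 1 was called, 678 had an unadjusted p under 0.05 where 676.2 would by chance, and the median difference was -0.325 points. The count was 1 with edgeR and 0 with limma on percent levels. Aldh1l1, whose promoter drives the tag, had 77.9% ± 2.61 5mC in input and 77.2% ± 1.06 in the positive fraction. Rlbp1, the retinaldehyde-binding protein of Müller glia, had 64.3% ± 6.78 and 60.2% ± 4.76, and Glul, their glutamine synthetase, had 58.3% ± 11.7 and 64.6% ± 21.0 on at least 54 calls. Nrl, the rod transcription factor, had 8.96% ± 8.12 and 7.88% ± 10.7 on as few as 26 calls in a library. Among the genes that write and remove 5mC, Dnmt1 had 82.7% ± 4.92 and 77.6% ± 5.23, Dnmt3a 44.8% ± 2.99 and 41.8% ± 5.34, Tet1 73.3% ± 4.64 and 69.5% ± 3.06, Tet2 71.5% ± 2.81 and 71.4% ± 4.08, and Tet3 39.5% ± 0.945 and 44.5% ± 3.81. None of these genes was called (quasi-binomial adjusted p of 0.966 or higher). Changes of 20 points were called in 62% of simulated gene bodies, so smaller differences in single genes were often not detectable at this depth.

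None of the gene lists differed between the fractions in gene body 5mC. All 17 lists had a cameraPR adjusted p of 0.979, the lowest with estimated correlation was 0.811, and the lowest with fry was 0.573. Of 22 Müller glia genes tested, 11 were higher and 11 lower in the positive fraction, among them Vim, an intermediate filament (47.2% ± 13.9 in input and 59.1% ± 9.58 in the positive fraction), and Car2, a carbonic anhydrase (34.0% ± 6.93 and 22.6% ± 8.56). Members higher and lower numbered 6 and 9 for rod genes, 3 and 4 for cone genes, 6 and 7 for bipolar genes, 6 and 5 for amacrine genes, 5 and 3 for ganglion cell genes, 3 and 2 for horizontal cell genes, 5 and 2 for microglial genes, and 6 and 5 for vascular genes. They numbered 0 and 5 for astrocyte genes, 4 and 3 for pigment epithelium genes, 3 and 8 for the DNA methylation machinery, 6 and 5 for reactive gliosis, 2 and 4 for neurogenic factors, 11 and 8 for imprinted genes, 4 and 1 for housekeeping genes, and 8 and 3 for Hox genes. Mean and median differences had opposite signs for bipolar, amacrine, vascular and reactive gliosis genes, and the direction of the test was opposite to both for ganglion and horizontal cell genes. In each list 0 genes were called by the quasi-binomial test when adjusted over the list alone and 0 over all genes.

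CpG-dense gene ends were compared because silencing of genes by methylation is best known there. Of 3695 ends tested for 5mC, 0 were called by the quasi-binomial test, 203 had an unadjusted p under 0.05 where 184.75 would by chance, and edgeR and limma called 0. The end of Sox9, a transcription factor of Müller glia, had 6.26% ± 8.73 5mC in input and 0.931% ± 0.938 in the positive fraction (SD, n = 3), and that of the Notch1 receptor 1.48% ± 1.63 and 3.71% ± 3.07. The end of Plagl1, an imprinted zinc finger gene, had 39.4% ± 4.61 and 70.6% ± 28.7 on as few as 19 calls, and that of Cdkn1c, an imprinted cell cycle inhibitor, 27.4% ± 8.10 and 35.2% ± 15.3. The end of Tet3 had 9.18% ± 2.43 and 7.54% ± 7.24, and that of Glul 0.494% ± 0.855 and 0.203% ± 0.352. All had a quasi-binomial adjusted p of 0.728 or higher. Only 8 lists had the 2 members needed for a test. They had from 2 (DNA methylation machinery) to 12 (Hox) members tested, with 5 of 28 for Müller glia. Rod, cone, bipolar, amacrine, microglial, vascular, astrocyte, pigment epithelium and housekeeping lists were not tested at ends. For the 8 lists, the cameraPR adjusted p ran from 0.656 to 0.896, and the lowest was 0.828 with estimated correlation and 0.774 with fry. The quasi-binomial test called 0 members of these 8 lists when adjusted over the list alone. Mean and median differences had opposite signs for the ends of imprinted genes, and the direction of the test was opposite to both for reactive gliosis.

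In the 2 kb tiles deep enough to test, and for the sum of both marks at gene ends and in gene bodies, no region was called. There were 1284445 tiles of 2 kb with a CpG position seen in any library. Of these, 4712 met the minimums for 5mC and 2433 those for 5hmC, so most of the genome was not tested in tiles of this size. Of 4712 tiles of 2 kb tested for 5mC, the quasi-binomial test called 0, with 295 at an unadjusted p under 0.05 where 235.6 would by chance, and limma on percent levels called 0. In the BS libraries, 0 of 4058 gene ends were called, with 228 at an unadjusted p under 0.05, and 0 of 14303 gene bodies, with 713. For both, edgeR and limma on percent levels called 0. With tiles of 10 kb, 1 of 87294 was called for 5mC. This tile, on chromosome 8 from 83990001 to 84000000, covers parts of Prkaca, the catalytic subunit of protein kinase A, and Samd1, a reader of unmethylated CpG islands, and had 35.8% ± 3.36 5mC in input and 10.7% ± 0.277 in the positive fraction (quasi-binomial adjusted p = 0.0281).

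The 5hmC levels of single genes were then compared between the fractions. One gene body was called. Slc22a7, which encodes an organic anion transporter, had a 5hmC level of 36.1% ± 3.19 in input and -18.5% ± 3.36 in the positive fraction (SD, n = 3), a difference of -54.6 points with SE 3.33 (limma adjusted p = 0.0179). A negative level means that more calls were methylated in oxBS than in BS libraries, which no true share of 5hmC can give. The Slc22a7 gene body lies on chromosome 17 from 46433185 to 46437477 and had as few as 36 calls in a library. Its 5mC was 26.0% ± 7.23 in input and 57.4% ± 9.10 in the positive fraction (quasi-binomial adjusted p = 0.693). Leaving out any 1 of the 6 samples left the Slc22a7 difference at -56.0 to -52.7 points and its limma adjusted p at 0.0820 to 0.221, above the threshold. With the animal as a block the difference was -54.6 points and the adjusted p 0.479.

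No other 5hmC difference was called with limma. Of 13319 gene bodies, 708 had an unadjusted p under 0.05 where 665.95 would by chance. Weighting limma by coverage called 1 gene body and the quasi-binomial interaction 2, and Slc22a7 was not among them. The counts were 0 of 2013 gene ends, with 74 at an unadjusted p under 0.05, and 0 of 2433 tiles, with 94, and weighted limma called 0 of both. For 5hmC in gene bodies the cameraPR adjusted p of the 17 lists ran from 0.778 to 0.893, with the lowest at 0.922 with estimated correlation and 0.934 with fry. For the ends of 8 lists, with 2 to 7 members tested each, it ran from 0.665 to 0.911, with the lowest at 0.911 with estimated correlation and 0.656 with fry. Of 21 Müller glia genes, 9 were higher and 12 lower, of 12 rod genes 6 were higher and 6 lower, and for several lists mean and median differed in sign, namely rod, amacrine, ganglion cell, horizontal, neurogenic and imprinted genes in bodies and Müller glia genes at ends. Pde6h, the inhibitory subunit of cone phosphodiesterase, had a gene body 5hmC of -2.15% ± 6.73 in input and 20.9% ± 7.84 in the positive fraction (limma adjusted p 0.832 over all genes and 0.0275 adjusted over the list alone). The end of Cdkn1c had 14.9% ± 7.05 and -7.67% ± 9.93 (limma adjusted p 0.917 over all ends and 0.0209 adjusted over the list alone, of which 2 members were tested). In the other lists limma called 0 genes adjusted over the list alone.

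Within each fraction, BS and oxBS libraries were compared to find gene bodies with 5hmC. The DNA demethylase gene Tet3, whose product converts 5mC to 5hmC, carried 25.5% ± 1.73 5hmC in input and 25.3% ± 5.43 in the positive fraction (SD, n = 3). Dnmt3a, a de novo methyltransferase, carried 22.4% ± 1.32 and 22.6% ± 6.21, Tet2 16.2% ± 2.00 and 17.3% ± 6.58, and Tet1 9.44% ± 6.39 and 11.5% ± 4.52, while Dnmt1, the maintenance methyltransferase, had 1.17% ± 8.94 and 4.47% ± 12.6 and was called in neither fraction. Among rod genes, Sag, the rod arrestin, carried 33.4% ± 10.6 and 26.7% ± 9.15 and Pde6a, a phosphodiesterase subunit, 26.0% ± 1.76 and 21.8% ± 4.28. Samd7, a rod repressor, carried 24.1% ± 9.09 and 22.1% ± 5.96. Prph2, a protein of the outer segment discs, carried 25.8% ± 11.8 and 7.46% ± 5.80, called in input (quasi-binomial adjusted p = 0.00572) and not in the positive fraction (0.149), and the difference between the fractions did not pass (limma adjusted p = 0.899). Among Müller glia genes, the glutamine transporter Slc38a3 carried 25.7% ± 11 and 27.4% ± 13.8, the retinol dehydrogenase Rdh10 22.6% ± 4.76 and 23.5% ± 6.11, the potassium channel Kcnj10 19.6% ± 9.30 and 15.5% ± 7.94, and Rlbp1 16.1% ± 8.64 and 18.3% ± 11. Prkca, the protein kinase C of rod bipolar cells, carried 16.2% ± 1.58 and 16.4% ± 1.88 on at least 2034 calls, and Aldh1l1 7.61% ± 4.33 and 7.13% ± 2.06. Apart from Dnmt1 and Prph2, each of these genes was called in both fractions.

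BS levels were called above oxBS levels in more than 1 of 2 gene bodies. Called or not, the mean BS level was the higher in 94.6% of gene bodies in input and 94.5% in the positive fraction. The quasi-binomial test called 7505 of 13905 gene bodies in input, 7500 of them higher in BS and 5 lower, with a median difference of 8.95 points, and 5152 differed by 10 points or more. In the positive fraction it called 7434 of 13761, 7425 higher and 9 lower, with a median of 9.33 points, and 5301 differed by 10 points or more. The counts were 7551 and 7533 with edgeR and 6332 and 6521 with limma on percent levels. Relative to each library's genome-wide level, 1440 gene bodies were called in input, 1334 higher and 106 lower, and 1242 in the positive fraction, 1162 higher and 80 lower, so most calls shared the shift of the whole genome. Of 13319 gene bodies tested in both fractions, 5695 were called in both, where independent lists would share 4074. Most calls shared the genome-wide shift, and a call also depends on the depth of the gene body. An overlap above 4074 therefore does not by itself show a 5hmC pattern of single genes common to both fractions. Across genes, which are not independent replicates, the 5hmC levels of the fractions correlated with Pearson's r of 0.552 and Spearman's rho of 0.557, and the 5mC levels with an r of 0.944. The calls included 15 and 14 of 21 Müller glia genes in input and the positive fraction, 11 and 10 of 12 rod genes, 8 and 8 of 11 genes of the DNA methylation machinery, and 0 and 0 of 11 Hox genes.

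The gene bodies called in both fractions were ranked by the mean of their 5hmC levels after the data were seen. H3f3a, which encodes histone H3.3, carried 28.5% ± 6.80 in input and 63.8% ± 4.49 in the positive fraction (SD, n = 3; limma adjusted p of the difference 0.366). Ywhae, a 14-3-3 protein, carried 45.4% ± 6.77 and 28.0% ± 8.58, Pcbp2, an RNA-binding protein, 39.4% ± 3.32 and 33.4% ± 8.0, Fem1b, a ubiquitin ligase adaptor, 28.3% ± 5.99 and 42.5% ± 5.36, and Ppm1d, a phosphatase, 35.1% ± 7.38 and 35.7% ± 2.87. Ube2n, Slc25a33, Nap1l1, Septin7 and Pkm followed, the last of which, a pyruvate kinase, carried 31.7% ± 7.59 and 33.5% ± 6.91. These 10 gene bodies were short in calls, with 34 to 88 in the library with the fewest, and a ranking by level favours genes with large counting error.

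Gene lists were further compared with all other gene bodies in the level of each mark, a comparison chosen after the data were seen. Gene bodies were not matched for CpG density or length, and 5mC fell with CpG density across tiles. Differences tied to density or length were therefore not separated from those of the lists. Rod genes carried 51.4% ± 1.20 5mC in input and 49.3% ± 0.957 in the positive fraction (SD, n = 3), against 71.5% ± 0.186 and 70.8% ± 0.234 in all gene bodies, and 16.8% ± 1.53 and 17.3% ± 3.03 5hmC against 9.80% ± 0.191 and 10.3% ± 0.247. The rod list had less 5mC (cameraPR adjusted p 5.88e-05 in input and 4.24e-05 in the positive fraction) and more 5hmC (0.00215 and 0.00128) than other genes. Müller glia genes carried 62.9% ± 1.56 and 61.9% ± 0.810 5mC, less than other genes in both fractions (0.00612 and 0.00509), and 11.9% ± 1.40 and 11.9% ± 0.916 5hmC (0.0818 and 0.696). Hox genes, which pattern the body axis and not the retina, had 4.00% ± 0.344 and 4.41% ± 0.578 5mC (8.72e-07 and 9.46e-07) and 1.03% ± 0.746 and 0.465% ± 0.373 5hmC (3.72e-05 and 1.83e-05), less of both marks than other genes. Less 5mC was also found in amacrine genes, with 58.7% ± 0.688 and 58.2% ± 0.686 (9.11e-05 and 8.59e-05), ganglion cell genes, with 47.8% ± 0.659 and 48.3% ± 2.77 (0.00169 and 0.00140), horizontal cell genes, with 45.8% ± 2.59 and 41.7% ± 1.91 (0.00612 and 0.0113), and neurogenic factors, with 36.2% ± 0.672 and 34.6% ± 2.48 (0.00219 and 0.00106). Astrocyte genes passed in the positive fraction, with 48.8% ± 2.21 (0.0435), and not in input, with 49.6% ± 1.94 (0.122), a contrast that was not itself tested. Imprinted genes carried 6.5% ± 0.624 and 6.15% ± 1.47 5hmC, less than other genes (0.0321 and 0.00294). No difference from other genes in either fraction passed for the 5mC of cone genes (73.2% ± 0.820 in input), bipolar genes (66.8% ± 2.56), microglial genes (78.9% ± 0.896), vascular genes (76.0% ± 2.29), pigment epithelium genes (76.1% ± 1.77), the DNA methylation machinery (62.9% ± 1.27), reactive gliosis (67.3% ± 0.973) and housekeeping genes (39.3% ± 5.90), of which 4 were tested. Every call of this comparison held with an estimated correlation, under which the 5hmC of Müller glia genes in input also passed (0.0452).

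**Figure D3:**
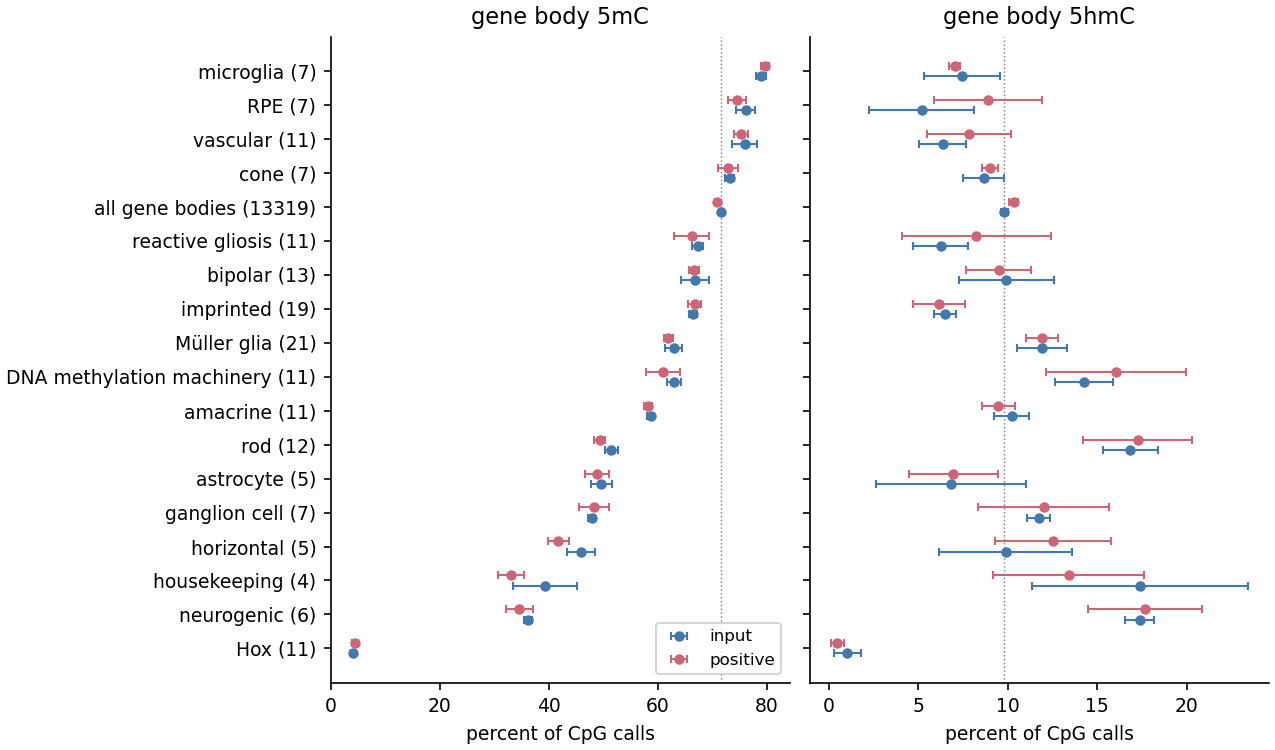
The x axes give gene body 5mC and 5hmC as percent of CpG calls for the 17 gene lists and all gene bodies, with points for the mean and bars for the SD of 3 animals in the input and positive fractions, and the dotted line for all gene bodies in input. Rod genes had 51.4% and 49.3% 5mC and 16.8% and 17.3% 5hmC, and Hox genes 4.00% and 4.41% 5mC.

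Since BS and oxBS libraries were made from the same DNA, a gene whose 5mC differed between the fractions would show the difference in both kinds of library. Across 13319 gene bodies the differences in oxBS libraries had an SD of 5.14 points and those in BS libraries an SD of 4.14 points. Across genes, which are not independent replicates, the differences correlated with a Pearson's r of -0.00722 and a Spearman's rho of 0.00205, and 49.9% of genes had the same sign in both. The levels themselves correlated between the fractions with an r of 0.944 for 5mC. Myo15b, with -24.7 points in oxBS and -7.28 points in BS libraries, was lower in both. An exchange of 5mC for 5hmC would leave the BS level as it was and would not show in this comparison.

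**Figure D4:**
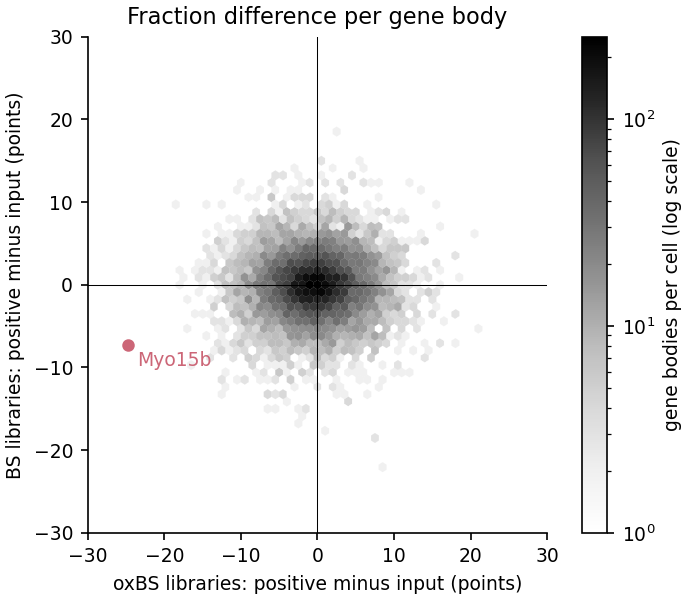
Shading gives the number of gene bodies per cell on a log scale, out of 13319, with the positive minus input difference in percentage points in oxBS libraries on the x axis and in BS libraries on the y axis, as means of 3 animals. Myo15b is marked by a point. Gene bodies beyond the axis limits are not drawn, such as Mtfr2 with 33.1 points in oxBS libraries. The cloud has no tilt, with a Pearson's r of -0.00722 across genes.

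The 5hmC level of the X chromosome differed between the animals more than that of any autosome did. In animal 12, X 5hmC was 5.60% in input and 6.30% in the positive fraction, against 3.00% and 3.24% in animal 40 and 3.21% and 2.99% in animal 55. The autosomal 5hmC of the same samples was 8.42% and 8.89%, 8.07% and 9.02%, and 8.56% and 8.51%. The X 5hmC values of input spanned 2.61 points and those of the positive fraction 3.31 points, against at most 0.864 points on chromosome 3 and 0.940 points on chromosome 4 for the autosomes. The 5mC level of the whole X was 76.1% and 75% in animal 12, 75.8% and 75.4% in animal 40, and 75.5% and 75.7% in animal 55. CpG-dense gene ends on the X had 16.4% and 16.6% 5mC in animal 12, 43.1% and 41.7% in animal 40, and 43.1% and 41.8% in animal 55. The X drew 1.83% to 1.89% of the calls of animal 12, 3.49% to 3.76% of those of animal 40 and 3.70% to 3.81% of those of animal 55. The Y drew 0.204% to 0.216% of the calls of animal 12 and 0.0133% to 0.0190% of those of animals 40 and 55. The labels used here do not state the sex of the animals. No p-value was computed between single animals, and comparisons of animal 12 with the others by counting error are given under other observations.

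**Figure D5:**
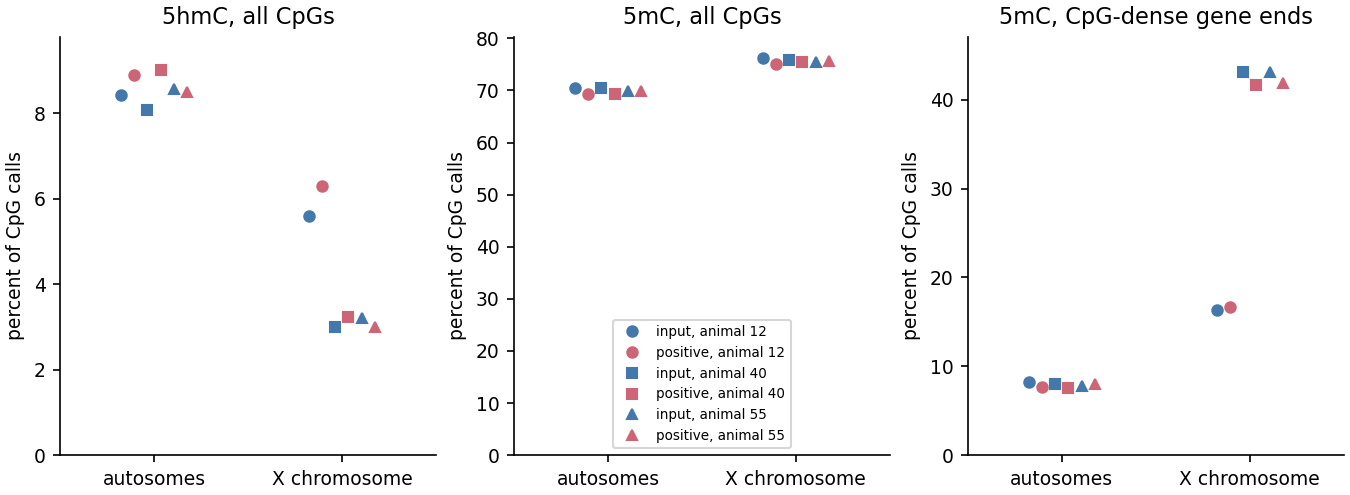
The y axes give 5hmC, and 5mC at CpG-dense gene ends, as percent of CpG calls on autosomes and on the X chromosome, with a symbol per animal and a colour for the input or positive fraction. X 5hmC was 5.60% and 6.30% in animal 12 and 2.99% to 3.24% in animals 40 and 55.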

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

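The tests weighed here on Myo15b and Slc22a7, and the other splits of the samples, were chosen after their results were seen, while the single-sample omissions and the block were planned. Slc22a7 stood out because the effect of chemistry differed between the fractions by -54.6 points in its gene body (limma), from 36.1% to -18.5% 5hmC. Mitochondrial DNA stood out because calls on it, which entered the genome-wide levels but were not compared on their own in the report, were methylated at levels above those a count of 0 allows. Counting all calls, those at positions above 6 calls included, the highest library had 5.01% methylated mitochondrial calls, the positive oxBS library of animal 55, and the lowest 2.39%, the input oxBS library of animal 12. Without the positions above 6 calls these libraries had 5.20% and 1.89%. Over 6 BS libraries the pooled share was 3.73% (Wilson 95% interval 3.36 to 4.13, 9445 calls) and over 6 oxBS libraries 3.15% (2.75 to 3.61, 6437 calls), again of all calls. No control DNA was among the files, so incomplete conversion of cytosine and true methylation of mitochondrial DNA were not tested against each other.

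The single gene bodies called between the fractions were weighed as 1 pattern. For Slc22a7, a positive-fraction level of -18.5% ± 3.36 lies below any true share of 5hmC, so counting noise on as few as 36 calls may account for part of it. Within 200 bp bins covered in both fractions, the Slc22a7 difference in oxBS libraries was 26.3 points (19.2 to 30.7 without any 1 library) of 23.4, so the positions covered did not make it, and in BS libraries it was -9.13 (-17.2 to -2.81 without any 1 library) of -17.6, and a real change stays open. Sampling of different positions could account for most of the Myo15b difference, because within 200 bp bins covered in both fractions -3.25 points remained, from -4.24 to -1.96 when any 1 library was left out. The Myo15b difference was -7.28 points in BS and -24.7 in oxBS libraries, but the gene was picked for the latter, so a loss of 5mC with and without a gain of 5hmC cannot be told apart.

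The number of ways to split 6 samples into 3 and 3 is 10, too few for a share under 0.05. The count of gene bodies called was 1 for 5mC and 1 for 5hmC in the real split and at most 0 in any other. It was 0 in the real split and at most 0 in the others for 5mC at gene ends and in tiles, for the sum of both marks at gene ends and in gene bodies, and for 5hmC at gene ends and in tiles. For BS against oxBS the real splits gave 7505 gene bodies in input and 7434 in the positive fraction and the others at most 0.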

How the results depend on the processing

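Summing both chemistries was the alternative chosen after the data were seen. Of 201 comparisons of 16 main results with alternatives, 173 stayed close to the first value, by the size of a count or level alone, and 28 moved. Equal counts did not always hold the same genes: for 5hmC weighted limma called Zzz3, higher by 34.0 points, in place of Slc22a7, and for 5mC Ccdc177 was called in place of Myo15b without the positive sample of animal 40. Of 1812 comparisons of 140 single genes, list members and regions, 1754 kept their direction and side of the threshold or stayed close, 39 moved, 19 lost the threshold and 0 reversed. Gene bodies called for 5mC numbered 1 at first, 0 with at least 5 calls per position (83 tested), 3 with 10 positions and 100 calls per region (8183 tested), 0 with no region minimum (17948 tested), 0 with limma, 0 with 4 kb flanks (17756 tested) and 0 to 1 without 1 sample. Tiles called numbered 1 of 87294 at 10 kb. Gene bodies called for 5hmC numbered 1 at first, 0 with the animal as a block, 0 with 10 positions and 100 calls (8053 tested), 0 with no region minimum (17779 tested), 2 with the interaction, 0 with 4 kb flanks and 0 to 0 without 1 sample. For BS against oxBS, at least 5 calls per position left 0 of 78 gene bodies in input and 1 of 71 in the positive fraction, where few regions remained. Centring on the genome level left 1440 and 1242, a shift its construction removes, and counts without 1 sample ran from 5524 to 5673 and from 5342 to 5586, with fewer samples. The genome-wide 5mC difference was -1.23 points with at least 5 calls, 0.40 on positions covered in all 12 libraries, and -0.942 to -0.592 without 1 sample, and the 5hmC difference was 0.936 on the shared positions and 0.289 to 0.624 without 1 sample. Apart from the changes explained by fewer regions or samples, the cause was not tested. With the animal as a block, the pairing left the genome-wide differences at -0.710 and 0.449 (exact sign-flip p = 0.5 for both, 0.25 being the smallest possible), ended the Slc22a7 call (adjusted p 0.479), kept Myo15b (0.0270), and gave 7320 and 7375 gene bodies for BS against oxBS. No list passed in any setting run. At least 10 calls per position gave no value, since positions above 6 calls were dropped. At least 5 calls gave none for gene ends, for tiles or for 5hmC in gene bodies, nor did 10 positions and 100 calls for the sum of marks or 5hmC at gene ends and 5hmC in tiles, each with fewer than 50 regions. At the real depth and spread, changes of 20 points were called in 62% of simulated gene bodies for 5mC and 8% for 5hmC.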

Other observations

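The tests of the X chromosome, of the likeness of the fractions and of summed chemistries were chosen after the results were seen, and the other settings were planned. Several regions were called under 1 or 2 alternatives and not at first. With at least 10 positions and 100 calls, Ccdc177, a coiled-coil gene, differed in gene body 5mC by -28.4 points and Usp42, a deubiquitinase gene, by -19.4 points (adjusted p = 0.0440 for both), and Ccdc177 was also called without the positive sample of animal 40 (-33.4 points, adjusted p = 0.0394). Zzz3, a zinc finger gene, differed in 5hmC by 34.0 points with weighted limma (adjusted p = 0.0295) and with the interaction (0.00234), and Syncrip, an RNA-binding protein gene, by -43.5 points with the interaction (0.0171). With both chemistries summed, Myo15b differed by -15.8 points (adjusted p = 0.00972), and a 10 kb tile on chromosome 17 from 26910001 to 26920000 in the kinesin gene Kifc5b had 31.5% ± 3.48 in input and 64.0% ± 3.6 in the positive fraction (SD, n = 3; quasi-binomial adjusted p = 0.0362). Positions covered in all 12 libraries had a 5hmC level of 0.489% ± 0.406 in input and 1.42% ± 0.982 in the positive fraction.

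Low depth alone may hide differences of single genes. An SD of 2 points among true 5mC differences over gene bodies, without a matching change of 5hmC, would have shown in a covariance between the chemistries. Such a covariance cannot show a shift common to all gene bodies, and it leaves room for larger differences in a minority of them. The covariance of the fraction difference between oxBS and BS libraries over 13319 gene bodies was -0.154 (SE 0.281, jackknife over chromosomes), and its upper 95% limit of 0.397 allows an SD of 0.630 points among true differences in the level common to both chemistries. In the deepest 3330 gene bodies the covariance was 0.135 and the SD allowed 0.594 points. Nuclei of other cells carried over with the beads could make the fractions alike, and rod genes, which differed by -2.08 points of 5mC (lower in 3 of 3 animals, exact p = 0.1) where all gene bodies differed by -0.731 (3 of 3, exact p = 0.1) and horizontal cell genes by -4.11 (3 of 3, exact p = 0.2), cannot settle it without a profile of pure Müller glia, so carry-over and a true likeness cannot be told apart. An exchange of 5mC for 5hmC stays open.

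The shares of calls argue against animal 12 having as many X chromosomes as animals 40 and 55. The X share of its calls was 0.541 of theirs, comparing its highest library with their lowest, and its Y share was 0.204% to 0.216% against 0.0133% to 0.0190%. Lower depth on its X does not account for its higher X 5hmC, which lay 14.5 counting SEs above the next sample, nor does stronger oxidation, since its lowest autosomal 5hmC lay below the highest of the others (-0.600 points). If animals 40 and 55 had a second X, its gene bodies would carry -0.132% to 0.638% 5hmC in input and -0.342% to 0.334% in the positive fraction, and its dense gene ends 69.8% and 66.7% to 67.0% 5mC, which could be a second X nearly without 5hmC. The ends of Xist, the RNA gene that silences an X, were methylated in 87.7% of 65 calls in animal 12 (Wilson 95% interval 77.5 to 93.6), 43.8% of 146 calls in animal 40 (36.0 to 51.9) and 39.7% of 184 calls in animal 55 (32.9 to 46.9). That the second X is nearly without 5hmC is a hypothesis from 1 animal against 2.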
